A study of Spinacia oleracea and Daucus carota and Theobroma cacao with 5 samples.

How the data were processed

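Small RNA libraries of cacao (Theobroma cacao) leaf, spinach (Spinacia oleracea) leaf and carrot (Daucus carota) leaf and root were analysed. Per the labels' protocols, pools of leaves or roots were frozen, total RNA was extracted with Trizol for spinach and carrot and with a Purelink kit for cacao, and libraries were made with the NEBNext small RNA kit and sequenced on an Illumina HiSeq2500. The deposited values are counts: each file lists distinct sequences and the number of reads with that sequence, with no normalization by the authors. The submitters' processing notes name cutadapt and FastQC, without versions or settings. An aligner and a genome build are not given in the sources used here. The files held tags of 15 to 47 nt with no undetermined bases, every tag was listed 1 time, and the lowest count was 1. Adapter trimming, length limits and quality filters by the authors set which reads could be counted, and reads without a trimmed adapter or with longer inserts were not analysed here.

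The labels give 5 groups of 1 library. The spinach libraries are numbered in their titles but differ in age, so they were treated as 2 groups and not as replicates. There is therefore no estimate of the spread between plants, and no test between groups was run. Shares were given with Wilson intervals, RPM with exact Poisson intervals and ratios with exact conditional binomial intervals, all at 95%. A count of 0 was taken to allow up to 3 counts. That limit was 1.42 RPM in cacao leaf, 0.225 in spinach leaf at 5 weeks, 0.686 at 3 weeks, 0.253 in carrot leaf and 0.584 in carrot root, so rare families are bounded least well in cacao leaf.

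Conserved families were counted with 38 families of plant miRNA and TAS3 siRNA in 7 lists (phase, auxin, development, machinery, nutrient, defence and MYB, other eudicot families), and the matching background with 11 families, 6 of animals and 5 of Brassicaceae or monocots. A tag of 19 to 24 nt was assigned to a family when positions 2 to 17 of a listed mature sequence began exactly within its first 5 bases. Ends of the tag could differ, so variants of 3′ length and small shifts of the 5′ end were pooled within a family, and members of a family that differ outside the core were not separated. tRNA and rRNA pieces were tags that share 16 consecutive bases with any of 42 plant tRNA and rRNA sequences. Both sets of sequences were written from general knowledge, so species-specific forms can be missed, and the shares depend on the matching rule. The pattern listed for miR482/miR2118 allowed only G or T at the third base, and a wider pattern was counted as an alternative.

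Values were scaled to RPM, the read count relative to all deposited reads of the library. In the carrot pair and the spinach pair, families at 10 or more RPM in at least 1 of the 2 libraries were compared. The named families were those at least 2-fold apart with an interval that excludes 1, and families under 2-fold were counted by list with up to 4 examples, the most abundant first. miR156 and a few others under 2-fold were named in addition after their values were seen. Across leaves, the named families were the 10 most abundant of each library and those at 10 or more RPM in all leaf libraries of a species and under 1 in all of another. Outside the lists, the 3 most abundant tags of 20 to 24 nt per library were named. Median log2 ratios of lists with at least 3 measured families were set against 10000 random lists of unlisted 20 to 22 nt tags, each drawn within 50 ranks of a family's mean abundance, with 0.5 added to the tags' counts. Tag turnover counted tags at 10 or more RPM in at least 1 of a pair that differed 4-fold or more, and sharing counted tags at 5 or more RPM in both libraries over those at that level in at least 1. The groups, family lists, naming rule and the alternatives below, apart from those named as later, were fixed before the data were examined.

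Alternatives were the distinct tags in place of reads, leaving out tags read 1 time, tRNA and rRNA pieces or the 10 most abundant tags, shared 20-mers for tRNA and rRNA, families counted in and scaled to 20 to 24 nt reads, which leaves out their 19-nt tags, a median family ratio of 1, the full listed sequence, 1 mismatch in the core, thinning to the smaller library of a pair, no abundance filter beyond 10 reads over both libraries, limits of 50 RPM or 10-fold for turnover and 1 RPM for sharing. Scaling to reads outside the listed tRNA and rRNA and the wider miR482/miR2118 pattern were added after the data were seen. A planned restriction to tags that match a genome was not run because no genome was used here.

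The code was tested on simulated data. All of 2450 planted tags were assigned to their family (100%), and 0 of 100000 random tags were assigned to any. The planted tags carried the listed cores, so this checks the code only and does not measure how many species-specific forms are missed. For the carrot comparison of 21 families, 95.3% of intervals held the planted value with no change and 94.7% at a planted 4-fold change, and 100% of 4-fold changes and 0% of unchanged families were called. For the spinach comparison of 17 families, 95.8% and 94.9% of intervals held the planted value, and 99.97% and 0.118% were called. Of 200 tags changed 8-fold, 100% were found among 772 simulated tags of the carrot pair and among 446 of the spinach pair. The simulation draws counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.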

Results

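Small RNA was sequenced from 3 crop species grown under control conditions, in 5 libraries with 1 library in each group: leaf tips of immature green leaves from a cacao tree, leaf tips of spinach plants at 5 and at 3 weeks, whole leaves of 5-week-old carrot plants and whole roots of 6-week-old carrot plants. Each library came from a pool of leaves or roots. The study's stated purpose was to annotate the small RNA loci of these plants. The measured quantity was the read count of each distinct sequence tag. The cacao library held 2116716 reads in 792974 distinct tags, spinach leaf at 5 weeks 13342726 reads in 5931576 tags, spinach leaf at 3 weeks 4371899 reads in 1775154 tags, carrot leaf 11838968 reads in 3141541 tags and carrot root 5141061 reads in 2101378 tags. Between 83.3% and 84.4% of the distinct tags of a library were read 1 time. With 1 library per group no comparison below has a replicate check and no p-value was computed. Ranges in parentheses are 95% counting intervals. Levels are given as RPM, the read count relative to all reads of the library. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

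The small RNA length classes were compared first. Reads of 24 nt, the length of the small interfering RNA (siRNA) that guides DNA methylation at repeats, were the most frequent in all 5 libraries. No loci were determined, so not every 24-nt read need be siRNA. Spinach leaf had by far the highest share of 24-nt reads relative to the 21-nt class, to which most plant miRNAs belong. Spinach leaf held 4.89 reads of 24 nt per 21-nt read at 5 weeks (4.87 to 4.90) and 2.85 at 3 weeks (2.84 to 2.87). The ratio was 1.33 in cacao leaf (1.32 to 1.34), 1.12 in carrot root (1.12 to 1.13) and 1.03 in carrot leaf (1.03 to 1.03). Spinach at 5 weeks also had 2.48 reads of 23 nt per 21-nt read, against 1.41 at 3 weeks and 0.369 to 0.552 in the other libraries. The 24-nt class was made mostly of rare tags. Without tags read 1 time the ratio was 3.40 and 1.59 in the spinach libraries and 0.648, 0.589 and 0.659 in cacao leaf, carrot leaf and carrot root, so that the direction turned in those 3 libraries.

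**Figure D1:**
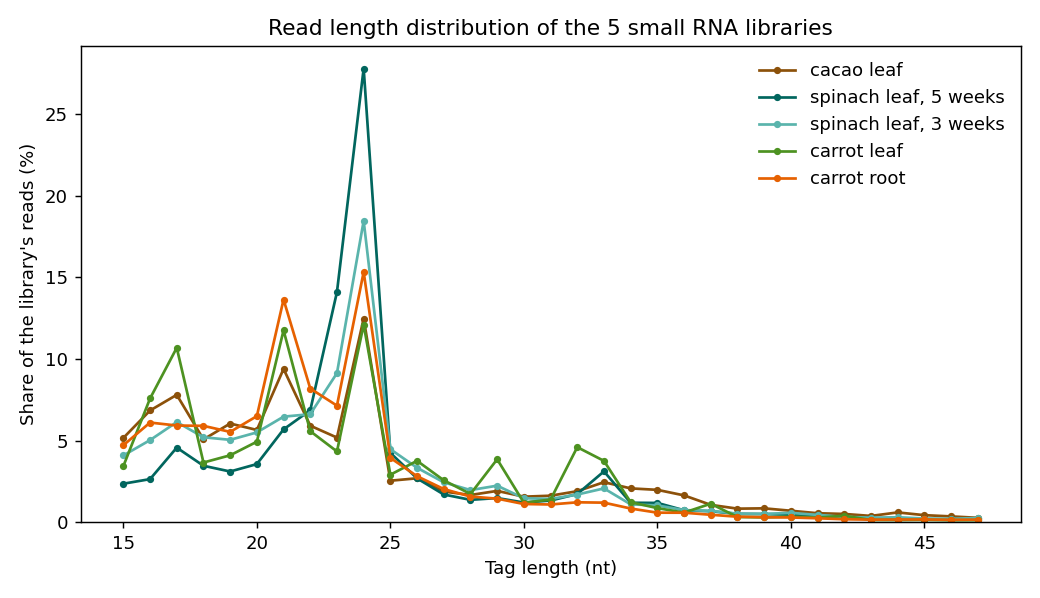
Share of each library's reads (y axis, %) at each tag length (x axis, nt), 1 line per library. All 5 libraries peak at 24 nt, and spinach leaf at 5 weeks has 4.89 reads of 24 nt per 21-nt read against 1.03 in carrot leaf.

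Adenine was the most frequent first base of 24-nt reads and uracil that of 21-nt reads in every library. Of 24-nt reads, 61.0% began with adenine in spinach leaf at 5 weeks, 59.7% at 3 weeks, 50.9% in cacao leaf, 45.3% in carrot leaf and 42.1% in carrot root, the base favoured by the Argonaute proteins that bind 24-nt siRNA. Of 21-nt reads, 50.5% began with uracil in carrot leaf, 47.4% in cacao leaf, 47.1% in carrot root, 39.8% in spinach leaf at 5 weeks and 34.6% at 3 weeks, the base most miRNAs begin with. By distinct tags adenine led the 21-nt class in spinach, at 37.3% against 29.5% for uracil at 5 weeks and 38.3% against 27.1% at 3 weeks. The widest counting interval of these shares, that of 21-nt reads in cacao leaf, ran from 47.2% to 47.7%.

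Pieces of tRNA and rRNA, counted with a partial list, made up 27.6% of carrot leaf reads, 15.8% of cacao leaf, 14.8% of spinach leaf at 3 weeks, 9.63% at 5 weeks and 5.796% of carrot root. The carrot leaf share came mainly from plastid tRNA, which took 18.8% of its reads (18.8 to 18.9), against 0.283% in carrot root (0.278 to 0.287), 5.24% in cacao leaf and 3.82% and 3.63% in the spinach libraries. Within it, the plastid aspartate tRNA alone took 18.01% of carrot leaf reads and 0.206% of carrot root reads. In carrot leaf 94.4% of its reads began at the 5′ end of the tRNA, 55.2% were 29 to 37 nt long and 35.9% were 16 to 18 nt long. Pieces of 15 nt could not be matched. Plastid rRNA took 3.58% of carrot leaf and 0.0865% of carrot root reads. Nuclear tRNA, by contrast, was 1.55% in carrot leaf and 1.62% in carrot root, and nuclear rRNA 3.67% and 3.81%.

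Conserved families were counted next, as 38 families of miRNA and TAS3-derived siRNA fixed in advance. They held 3.26% of cacao leaf reads (3.24 to 3.29), 1.73% of carrot leaf (1.72 to 1.74), 1.28% of spinach leaf at 5 weeks (1.28 to 1.29), 1.10% at 3 weeks (1.09 to 1.11) and 0.853% of carrot root (0.845 to 0.861). At 10 or more RPM, 27 families were present in cacao leaf, 21 in carrot leaf, 19 in carrot root, 16 in spinach leaf at 5 weeks and 15 at 3 weeks. As background of the matching, 11 families of animals, Brassicaceae and monocots reached at most 1.57 RPM in any library. With 1 mismatch allowed, the carrot shares were 2.78% in leaf and 1.89% in root. The full listed sequences alone gave 1.63% in cacao leaf, 0.607% and 0.549% in spinach leaf, 0.359% in carrot leaf and 0.254% in carrot root.

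In carrot, leaf and root differed most in miR157 and miR172, 2 of the 3 families of developmental phase. miR157, which represses SPL transcription factors, stood at 4361 RPM in leaf and 146 in root, a 29.9-fold difference (27.8 to 32.2). miR172, which represses AP2-like transcription factors, was 28.4-fold higher in leaf (19.4 to 43.2), at 149 against 5.25 RPM. miR858, which targets MYB factors of flavonoid synthesis, was 8.93-fold higher in leaf (7.60 to 10.6). In root, miR477 was 8.22-fold higher (6.84 to 9.94), at 102 against 12.4 RPM, and miR160, which represses auxin response factors, 2.51-fold higher (2.09 to 3.01). Of 21 families at 10 or more RPM in at least 1 of these 2 libraries, 7 were at least 2-fold higher in leaf, 2 were at least 2-fold higher in root and 12 differed by less than 2-fold.

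By list, 2 of the 3 phase families were higher in leaf, and the remaining family, miR156, was at 187 and 143 RPM. The median log2 ratio of the phase list was 4.83, above 99.6% of 10000 random lists of unlisted 20 to 22 nt tags, whose own median was 0.31. Here and in the lists below, draws for the most abundant families fell partly on a single tag, so these percentiles are descriptive and not a test. Of 4 auxin families measured, 1 was higher in leaf and 1 in root: miR167, which represses other auxin response factors, was 4.11-fold higher in leaf (3.95 to 4.29), opposite to miR160, while the TAS3 siRNA tasiR-ARF was at 70.4 and 35.6 RPM (ratio 1.98, 1.68 to 2.33) and miR390, its trigger, at 18.2 and 15.8. The auxin list's median log2 ratio was 0.60, above 84.4% of random lists (median -0.54). Of 7 development families, miR396, which represses growth-regulating factors, was 4.62-fold (4.21 to 5.09) and miR170/miR171, which targets GRAS factors of the shoot meristem, 2.01-fold higher in leaf (1.48 to 2.79). The other 5 differed by less than 2-fold, among them miR165/miR166, the regulator of HD-ZIP III factors, at 3778 RPM in leaf and 3897 in root, miR159, which targets GAMYB-like factors, at 2717 and 1665.2, and miR319, which targets TCP factors, at 123 and 137. The list's median was 0.34, above 66.1% of random lists (median -0.04).

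Of the machinery list only miR168, which represses the main miRNA-binding Argonaute, reached 10 RPM by the exact core, and it was 4.46-fold higher in leaf (4.23 to 4.70). This does not make miR403 of the same list rare in carrot. It was at 3.55 RPM in leaf and 8.95 in root by the exact core, but at 1962 and 3943 with 1 mismatch allowed. All 3 nutrient families measured differed by less than 2-fold: miR398, which targets copper/zinc superoxide dismutase, was at 1315 and 831 RPM, miR408, which targets plantacyanin, at 255 and 400, and miR395, which targets ATP sulfurylase, at 23.99 and 13.8. Their median log2 ratio was 0.66, above 86.6% of random lists (median 0.14). Of 2 defence and MYB families, miR858 was higher in leaf, and miR482/miR2118, which targets disease resistance genes, was at 151 and 78.6. Of the other eudicot families, miR477 alone was measured. Leaf and root also differed in plant age and in the plastid tRNA share given above.

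The median family ratio of leaf over root was 1.63, and setting it to 1 gave 6 families higher in leaf and 3 in root, with miR157 at 18.3-fold, miR172 at 17.4-fold and miR170/miR171 at 1.23-fold higher in leaf. In either pair this turns by construction every ratio between 1 and its median. With families both counted in and scaled to reads of 20 to 24 nt, which also left out their 19-nt tags, 12 of 24 families were higher in leaf and 1 in root, with miR160 at 1.90-fold higher in root. Ratios near 1 turned: those of miR165/miR166 and miR319 were 1.33 and 1.09 here and 1.26 and 1.17 scaled to reads outside tRNA and rRNA (a scaling chosen after seeing the data), and that of miR156 was 0.991 with the full listed sequence. That of miR164 turned from 1.11 to 0.987 with the leaf library thinned. With 1 mismatch allowed the counts were 6 and 3, and the calls for miR396, miR160 and miR170/miR171 ended: the main carrot form TTCCACGGCTTTCTTGAACTG then counted as miR396, which stood at 7795 and 5209 RPM (1.496-fold higher in leaf), miR160 was 1.62-fold higher in root and miR170/miR171 1.52-fold higher in leaf, while miR394 came to 2.08-fold higher in leaf, miR827 of the nutrient list to 3.98-fold (3.60 to 4.40) and miR403 of the machinery list to 2.01-fold (1.97 to 2.05) higher in root. Only miR477 was at least 2-fold higher in root in both counts. The miR170/miR171 call also ended with the leaf library thinned, at 1.90-fold. By the full listed sequences alone miR157 was 7.61-fold, under the 9.20-fold of miR858, miR396 2.55-fold and miR168 1.72-fold higher in leaf and miR319 8.42-fold higher in root, and miR170/miR171 had no value.

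**Figure D2:**
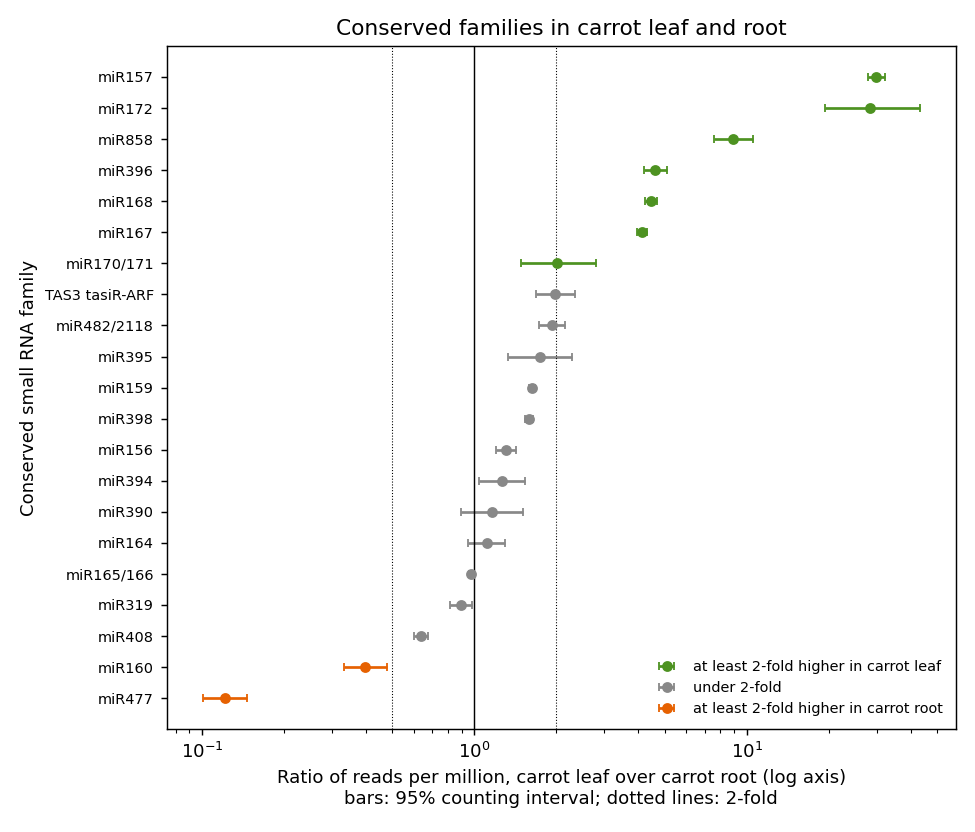
Ratio of RPM in carrot leaf over carrot root (x axis, log scale) for the 21 conserved families measured (y axis), with 95% counting intervals as bars and dotted lines at 2-fold, 1 library each. miR157 at 29.9 and miR172 at 28.4 lie farthest to the leaf side, and miR477, 8.22-fold higher in root, farthest to the root side.

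In spinach leaf, plants of 5 and 3 weeks were compared. The copper-responsive miR398 differed most, at 151 RPM at 5 weeks and 10.8 at 3 weeks, a 14.0-fold difference (10.5 to 19.2). miR172 was 3.29-fold higher at 5 weeks (3.15 to 3.43), at 1787 against 544 RPM. miR156, which keeps plants juvenile through SPL repression, leaned the other way, at 273 RPM at 5 weeks and 510 at 3 weeks, 1.87-fold higher at 3 weeks (1.77 to 1.97) and so under the 2-fold limit. Of 17 families measured, 5 were at least 2-fold higher at 5 weeks, 1 was at least 2-fold higher at 3 weeks and 11 differed by less than 2-fold.

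By list, 1 of 3 phase families was higher at 5 weeks, and miR157 was at 68.8 and 79.1 RPM. The list's median log2 ratio was -0.20, above 33.4% of random lists (median 0.52). Of 3 auxin families, miR393, which targets auxin receptors, was 3.20-fold (1.97 to 5.53) and miR160 2.12-fold (1.66 to 2.75) higher at 5 weeks, while miR167 was at 2660 and 1669 RPM. The auxin list's median was 1.08, above 98.6% of random lists (median -0.59), on 3 families of which miR393 had 18 reads at 3 weeks. Of 6 development families, miR394, which targets an F-box gene of leaf shape, was 2.05-fold higher at 5 weeks (1.61 to 2.64) and 5 differed by less than 2-fold, among them miR159 at 3727 and 5412, miR396 at 2249 and 1330 and miR165/miR166 at 1045 and 678 RPM. Their median was 0.45, above 80.3% of random lists (median -0.05). All 3 machinery families differed by less than 2-fold: miR162, which targets the Dicer-like enzyme that makes miRNAs, was at 482 and 439 RPM, miR403, which targets an Argonaute gene, at 214 and 168, and miR168 at 51.3 and 27.4, with a median of 0.35, above 65.6% of random lists (median -0.16). Of 2 nutrient families, miR398 was higher at 5 weeks and miR395 3.73-fold higher at 3 weeks (2.35 to 5.96), on 36 and 44 reads. No defence, MYB or other eudicot family reached 10 RPM.

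The median family ratio of 5 weeks over 3 weeks was 1.54. With families both counted in and scaled to reads of 20 to 24 nt, 3 were higher at 5 weeks and 3 at 3 weeks, and the ratios of miR157, miR162, miR403 and miR164 turned to 1.19, 0.855, 0.984 and 0.990. miR160 and miR394 came to 1.73-fold and 1.68-fold, and miR156 and miR319 to 2.14-fold and 2.12-fold higher at 3 weeks. In spinach the leading miR319 form was 1 base from the leading miR159 form. It had 69 reads at 5 weeks and 31 at 3 weeks, of 263 and 147 in the family. The leading miR159 form had 26916 and 13009. Whether that miR319 form is separate from miR159 was not tested, so miR319 need not be an independent call in this pair. With the median family ratio set to 1 the counts were 3 and 4, with miR398 at 9.12-fold and miR172 at 2.13-fold higher at 5 weeks, miR160 and miR394 down to 1.38-fold and 1.33-fold, and miR156, miR319 and miR159 at 2.88-fold, 2.63-fold and 2.24-fold higher at 3 weeks. By the full listed sequences alone miR172 was 6.80-fold (4.12 to 12.0) and miR160 3.93-fold higher at 5 weeks, while miR393 and miR395 had no value. That miR172 ratio rests on 24.9 and 3.66 RPM, a small part of the family's 1787 and 544. The counts were then 6 and 1, with miR396 at 2.18-fold and miR168 at 2.05-fold higher at 5 weeks, miR156 at 2.11-fold higher at 3 weeks and miR162 turned to a ratio of 0.994. Outside tRNA and rRNA reads miR394 was at 1.93-fold.

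**Figure D3:**
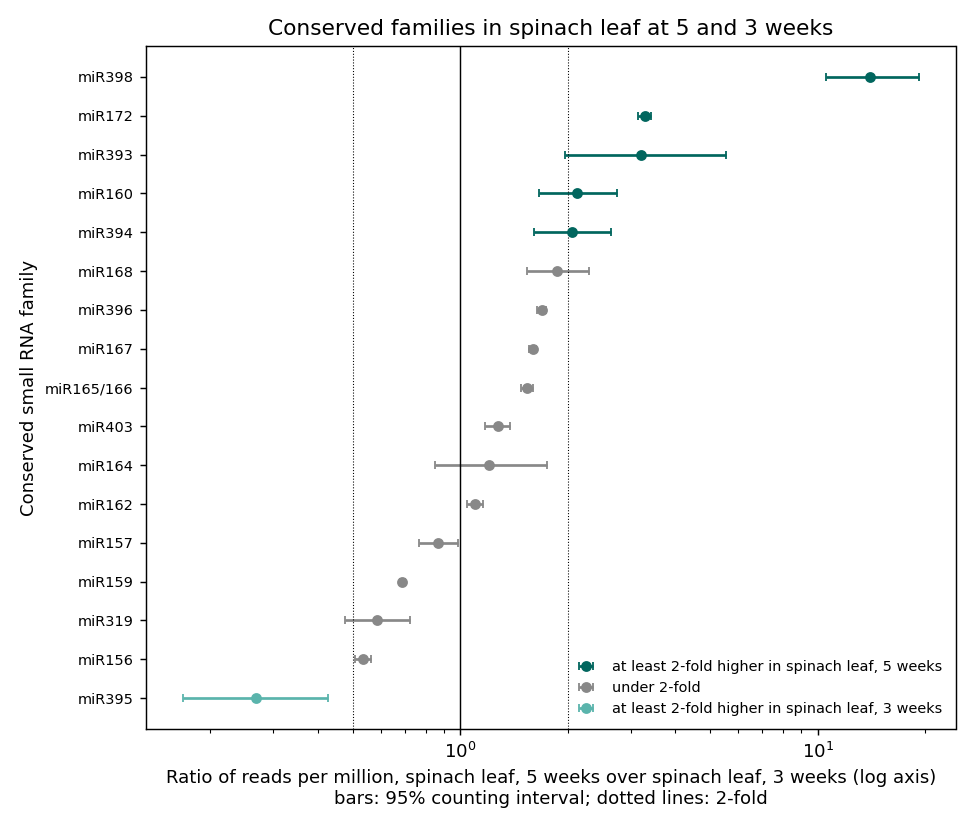
Ratio of RPM in spinach leaf at 5 weeks over 3 weeks (x axis, log scale) for the 17 conserved families measured (y axis), with 95% counting intervals as bars and dotted lines at 2-fold, 1 library each. miR398 lies at 14.0, and miR395, 3.73-fold higher at 3 weeks, at the opposite end.

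Across the leaves of the 3 species, 4 families were among the 10 most abundant in all 4 leaf libraries: miR159, miR165/miR166, miR167 and miR396. Cacao leaf was led by miR159 at 11234 RPM (11092 to 11378) and miR165/miR166 at 10657 (10518 to 10797), followed by miR396 at 5751 and miR167 at 1581. Its next families were miR162 at 490, tasiR-ARF at 475, miR482/miR2118 at 407, miR319 at 332, miR395 at 264 and miR530 at 216. The pattern listed for miR482/miR2118 left out a cytosine at the third base. With it, a choice made after seeing the data, the family was at 1876 RPM in cacao leaf and above miR167. In spinach, miR159, miR167, miR396 and miR172 led at 5 weeks, at 3727, 2660, 2249 and 1787 RPM. Carrot leaf was led by miR157 at 4361 (4324 to 4399), against 39.2 in cacao leaf and 68.8 and 79.1 in spinach. Carrot leaf also held miR168 at 1358 and miR398 at 1315 RPM, against 96.8 and 20.8 in cacao leaf. With 1 mismatch allowed, miR396 led carrot leaf at 7795, ahead of miR157 at 4622. By the full listed sequences alone, miR165/miR166 led carrot leaf at 942 and miR157 was at 154.

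Several families were abundant in the leaves of 1 species and under 1 RPM in those of another. Spinach had 3 tasiR-ARF reads and 6 miR390 reads over its 2 libraries. tasiR-ARF was 2806-fold higher in cacao (958 to 13631) and 415-fold higher in carrot leaf (142 to 2019), and miR390, which directs its production, 331-fold higher in cacao (150 to 910) and 53.9-fold higher in carrot leaf (24.3 to 148). miR482/miR2118, with 5 spinach reads, was 1443-fold higher in cacao (616 to 4455) and 535-fold in carrot leaf (229 to 1649), and miR858, with 3 reads, 265-fold (88.0 to 1308) and 1589-fold (543 to 7710). miR477 had no spinach reads, and was at least 83.7-fold higher in cacao and at least 73.3-fold higher in carrot leaf, taking 3 counts over both spinach libraries as the limit that a count of 0 allows (with counting error on both sides, lower limits of 63.96 and 58.88). Carrot leaf in turn had 3 reads of miR162, which was 1935-fold higher in cacao (660 to 9399) and 1860-fold higher in spinach (636 to 9021). miR399, which targets a phosphate homeostasis gene, was 46.6-fold higher in cacao than in carrot leaf (19.97 to 133). miR530 was at least 1275-fold higher in cacao than in spinach and at least 852-fold higher than in carrot leaf (lower limits 1033 and 690), and miR535 312-fold higher than in spinach (104 to 1538) and at least 209-fold higher than in carrot leaf (lower limit 167). These low levels all lay at or under the highest background family of the same species' leaf, 1.57 RPM in spinach and 0.507 in carrot, so the folds do not tell a low level from none. With 1 mismatch allowed, spinach reached 62.3 RPM for miR535 against 53.9 in cacao leaf, which ended that contrast. For miR482/miR2118 it reached 2.92, over the limit of 1, against 3576 in cacao leaf and 160 in carrot leaf, while those of miR390, tasiR-ARF, miR858, miR477, miR162, miR399 and the remaining ones of miR530 and miR535 stayed under 1. Species, cultivar, age and part of the leaf differed together, and cacao RNA was extracted with another kit.

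**Figure D4:**
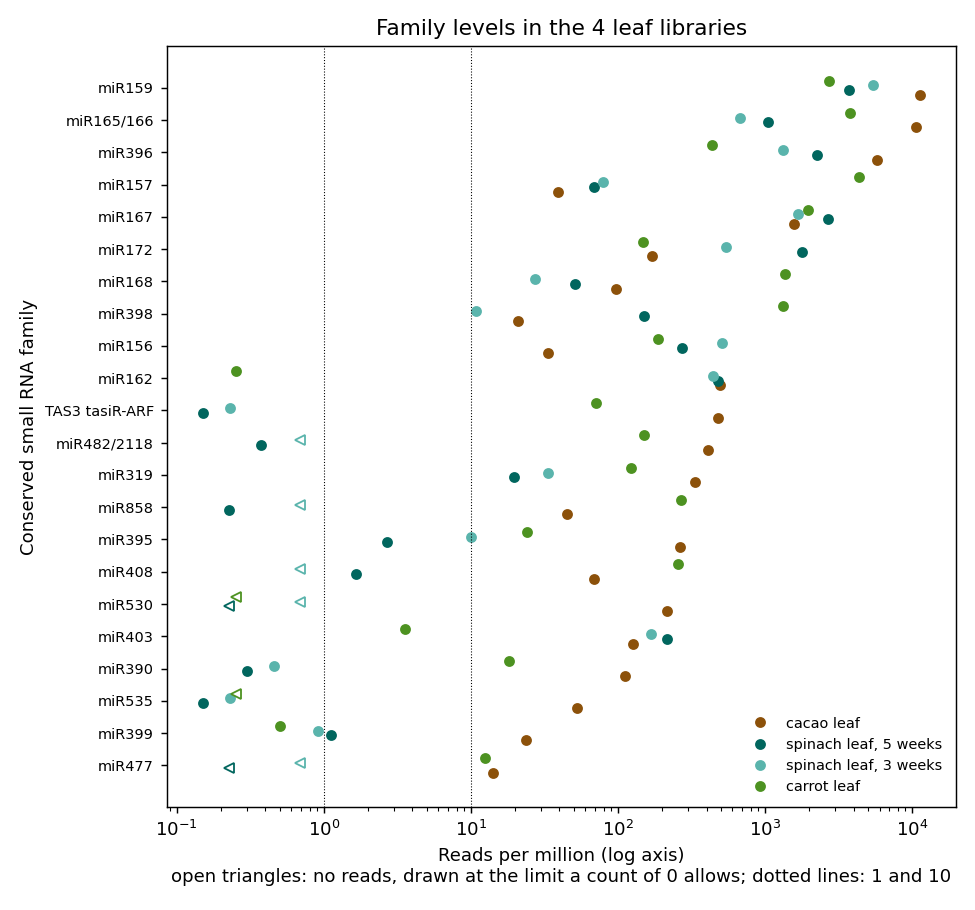
RPM (x axis, log scale) in the 4 leaf libraries (colours) for families among the 10 most abundant of a leaf library or under 1 RPM in a species (y axis), with open triangles for no reads, drawn at the limit a count of 0 allows. miR159 lies at 2717 or more in all 4 libraries, and tasiR-ARF lies at 475 in cacao and under 1 in both spinach libraries.

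The most abundant form of several families differed between species. miR172 was mostly CGAATCTTGATGATGCTGCAT in spinach (74.7% of its reads at 5 weeks and 71.5% at 3 weeks) and AGAATCTTGATGATGCTGCAT in cacao leaf (71.5%) and carrot leaf (66.5%). The leading miR165/miR166 form was CCGGACCAGGCTTCATTCCCC in both spinach libraries and TCGGACCAGGCTTCATTCCCC in cacao and carrot. miR159 was led by TTTGGATTGAAGGGAGCTCTG in carrot, at 45.7% of its leaf and 62.5% of its root reads, and by TTTGGATTGAAGGGAGCTCTA in cacao and spinach. The leading carrot miR168 was the 22-nt TCGCTTGGTGCAGGTCGGGACC, at 47.2% of leaf reads, where cacao and spinach had the 21-nt TCGCTTGGTGCAGGTCGGGAA. These forms were singled out after their values were seen.

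Outside the lists, the most abundant tag of 20 to 24 nt in both spinach libraries was AGTTACTAATTCATGATCTGGC, at 7710 RPM at 5 weeks and 5386 at 3 weeks. It was also at 2819 in cacao leaf and 1699 in carrot leaf, against 126 in carrot root. Its 22-nt relative AGTTACTAATTCATGATCTGGT was at 4839 and 2646 in spinach, and the 24-nt AGTTACTAATTCATGATCTGGCAT at 2822 in cacao leaf. CCCAAGATGAGTGCTCTCCT was at 2277 in spinach leaf at 5 weeks, CCTATGTCGCTTCGATTCGT at 2783 at 3 weeks and CCTTTGTCGCTCCGATTCGT at 4403 in cacao leaf. In carrot, TTAGGCTGTTGTGAGAAAGATT was at 2599 in leaf and 2006 in root, TTTCTCGAAATCTGATAAGCG at 2198 and 2663, and TTCATGGACGTTGATAAGATC at 2233 and 824, each with the 2 values in that order. The miR403-like TTAGATTCGCGCACAAACTCG, 1 mismatch from the listed core, was at 909 in carrot leaf and 2273 in carrot root. The carrot tag at 2233 in leaf was also at 801 in spinach leaf at 3 weeks, 193 at 5 weeks and 33.1 in cacao leaf. No genome was used, so loci and annotations of these tags are not given.

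Turnover of single tags was compared within species. Of carrot 21-nt tags at 10 or more RPM in leaf or root, 48.3% differed at least 4-fold between the organs (45.8 to 50.9, of 1481 tags), and of 24-nt tags 50.3% did (46.4 to 54.2, of 636). Among the 716 such 21-nt tags, 488 were higher in root and 228 in leaf. Between the spinach ages 13.3% of 21-nt tags (10.6 to 16.6, of 495) and 10.5% of 24-nt tags (8.28 to 13.1, of 622) differed 4-fold. Among the 66 such 21-nt tags, 51 were higher at 3 weeks and 15 at 5 weeks, so in both pairs more 21-nt tags were higher in the library with fewer reads. Among 24-nt tags 237 were higher in carrot root and 83 in leaf, and 31 at 3 weeks and 34 at 5 weeks in spinach. Organ and age differ between these pairs along with species, and the difference between pairs was not tested.

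Between species, a smaller share of 24-nt than of 21-nt tags was in both libraries, with separate intervals only in the pairs with spinach. Of tags at 5 or more RPM in cacao leaf or spinach leaf at 5 weeks, 14.0% of 21-nt tags (12.4 to 15.7) and 5.00% of 24-nt tags (4.17 to 5.98) were in both. For spinach and carrot leaf the shares were 7.47% (6.41 to 8.68) and 4.23% (3.42 to 5.22). For cacao and carrot leaf they were 7.74% (6.79 to 8.81) and 6.46% (5.34 to 7.81), with overlapping intervals. Shared tags outside the conserved families and the tRNA and rRNA list were 131 of 2700 compared at 21 nt and 81 of 1532 at 24 nt there. By that count the 24-nt share was not the lower one. It stayed lower for cacao and spinach (149 of 1641 against 93 of 2240) and for spinach and carrot leaf (106 of 2076 against 68 of 1937). Conserved families made up 46 of the 229 shared 21-nt tags of cacao and spinach, and none of the 112 shared 24-nt tags. Listed tRNA and rRNA pieces made up 34 and 19 of them, and most, 149 and 93, were in neither list. Only parts of the 18S, 25S and plastid 16S rRNA were listed, and nothing of the large plastid rRNA. Pieces of the unlisted parts would count in neither list, so these tags need not be other kinds of small RNA. Within species, carrot leaf and root shared 31.0% of 21-nt and 24.3% of 24-nt tags, and the spinach ages 40.4% and 39.1%.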

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

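The tags longer than 24 nt were singled out only after the data were seen, and no test was run on the values of this part.

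The comparisons above use tags of up to 24 nt, apart from length shares and tRNA and rRNA pieces. The longer tags below were counted as exact sequences, so a low value elsewhere does not make an RNA specific to a species. Those of cacao leaf and carrot leaf differ only within their first bases. That of spinach leaf at 3 weeks begins with a 21-nt carrot tag named above. This shorter tag was at 2233 RPM in carrot leaf and 801 in spinach leaf at 3 weeks. Each library's most abundant longer tag outside the tRNA and rRNA lists exceeded the 3 counts that a count of 0 allows. It had 8778 reads in cacao leaf (TCTGCTTTTATGTTATTTCGTACTGT, 4147 RPM there and at most 6.15 in any other library), 56113 in spinach leaf at 5 weeks (ATAAATCAAAGTATTTTGGACCTCTT, 4206 RPM, 2129 at 3 weeks and at most 1.42 outside spinach) and 16498 in spinach leaf at 3 weeks (TTCATGGACGTTGATAAGATCCTTC, 3774 RPM, 1941 at 5 weeks and at most 119 outside spinach). In carrot it had 74351 reads in leaf (TTTTTTTTTATGTTATTTCGTACTGT, 6280 RPM, 1081 in root) and 17341 in root (TCCATTGTCGTCCAGCGGTTAGGATA, 3373 RPM, 3542 in leaf).

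The families of the matching background that exceeded 3 counts were miR158, with 21 reads in spinach leaf at 5 weeks, 4 at 3 weeks, 6 in carrot leaf and 7 in carrot root, miR161, with 13 reads in spinach leaf at 5 weeks, and the animal miR-21, with 7 reads in spinach leaf at 5 weeks. The highest of these was 1.57 RPM.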

How the results depend on the processing

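Scaling to reads outside the listed tRNA and rRNA and the wider miR482/miR2118 pattern were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. The planned restriction to tags that match a genome was not run. With 1 library per value, a value is called moved when it leaves its own counting interval, which at these depths is narrow, and a count of families when it changes more than 1.5-fold, whichever families make it up. Of 109 alternative values of the main results 65 moved and 44 did not, and of 115 for the single families 37 moved and 78 did not, with no ratio of the 15 called families turning direction. All 15 stayed within their intervals after thinning and without the abundance filter. Unless stated, the cause of a shift was not tested. Depth limits rare families most in cacao leaf, the shallowest library.

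The 24-nt to 21-nt ratio, in the order cacao leaf, spinach leaf at 5 weeks, spinach leaf at 3 weeks, carrot leaf and carrot root, was 2.77, 8.80, 5.90, 2.73 and 2.23 by distinct tags, and 0.648, 3.40, 1.59, 0.589 and 0.659 without tags read 1 time. Without tRNA and rRNA pieces it was 1.39, 5.12, 3.12 and 1.14 in the libraries other than carrot leaf, and without the 10 most abundant tags 1.45 in cacao leaf, 2.99 in spinach leaf at 3 weeks and 1.19 in carrot root. By distinct tags, 24-nt tags began with A in 50.6%, 58.5%, 60.6% and 44.5% of cases in the 4 leaf libraries, and 21-nt tags with U in 35.5%, 29.5%, 27.1%, 36.2% and 40.7% in all 5. With shared 20-mers, a stricter match by construction, tRNA and rRNA shares were 10.1%, 6.74%, 9.28%, 17.4% and 3.02%.

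The conserved family share, in the same order, was 8.06%, 2.14%, 2.26%, 3.29% and 1.54% of 20 to 24 nt reads, 1.63%, 0.607%, 0.549%, 0.359% and 0.254% with the full listed sequence, and 3.82%, 1.37%, 1.16%, 2.78% and 1.89% with 1 mismatch. The wider miR482/miR2118 pattern gave 3.41% in cacao leaf and stayed within the interval elsewhere.

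Families at least 2-fold higher in carrot leaf numbered 12 counted in and scaled to 20 to 24 nt reads, which changes the tags, the families tested (24 against 21) and the denominator together, and 12 scaled to reads outside tRNA and rRNA, against 7, and those higher in root 1 and 1, against 2. Higher in spinach at 5 weeks were 3 counted in and scaled to 20 to 24 nt reads and 3 with the median family ratio set to 1, against 5, and at 3 weeks 3 and 4, against 1. Setting the median to 1 and leaving out tRNA and rRNA each multiply a pair's ratios by a constant, which by construction moves families near the limit across it.

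At 50 RPM, 40.9% of 21-nt and 62.3% of 24-nt carrot tags and 8.74% of 21-nt spinach tags differed 4-fold. A 10-fold limit, stricter by construction, gave 27.3% and 23.4% in carrot and 0.808% and 0.804% in spinach. At 1 RPM, 3.54% of 24-nt tags were shared by cacao and spinach, 4.77% by cacao and carrot leaf and 2.77% by spinach and carrot leaf. The 21-nt sharing values stayed within their intervals.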

Other observations

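The tests of spinach depth, of spinach miRNA recovery, of carry-over and of paired tags, and the values on runs of T, were chosen only after the related results were seen, and the label rule of the plastid test was tightened, and the carry-over test and the count of paired tags replaced, after a first value.

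The copper-responsive miR408 carried runs of T at its 3′ end. Of its reads in carrot root 45.6% (43.5 to 47.8) ended in TTTT, the leading form being TGCACTGCCTCTTCCCTTTTTTT, against 26.6% in carrot leaf (25.03 to 28.2) and 22.8% in cacao leaf (16.7 to 30.2). Whether these runs are tails or residues of trimming was not settled, since the trimming settings are not stated. The median over families with at least 100 reads was 1.25% in carrot root, 0.648% in carrot leaf and 1.55% in cacao leaf. miR170/miR171 in cacao leaf, at 25.7% (19.3 to 33.4), and miR393 in spinach leaf at 5 weeks, at 24.4% (18.7 to 31.3), were also high, and miR160 reached 11.8% in carrot root. miR157 of carrot leaf was led by the 19-nt TTGACAGAAGATAGAGAGC, at 47.7% of its reads, and miR167 of carrot leaf by the 19-nt TGAAGCTGCCAGCATGATC, at 34.3%.

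miR390 and tasiR-ARF were both near 0 in spinach. A spinach sequence variant was searched among 20 to 22 nt tags within 3 mismatches: at most 0.457 RPM were found for miR390 and 0.915 for tasiR-ARF, under the 10 that a variant form was set to reach. The highest upper limit for miR390 in a spinach library was 1.65 RPM against a lower limit of 15.9 in carrot leaf. The family was picked at under 1 RPM in spinach and 10 or more in carrot leaf, so this outcome was fixed by that choice. It shows only that a carrot leaf level would have been counted at the spinach depths. The other families had a median spinach to carrot leaf ratio of 0.277 at 5 weeks and 0.420 at 3 weeks. This was 16.7 times that of miR390 in the spinach library where the factor was lower. They were thus low as well, but less so. Because miR390 was picked for its low spinach level, this comparison cannot decide on low miRNA recovery. That spinach leaf makes little miR390 and tasiR-ARF remains a hypothesis found and tested on the same data. Forms with more than 3 mismatches, miRNA recovery and leaf age stay open.

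miR162 was near 0 in both carrot libraries, while cacao and spinach leaf had 439 RPM or more. Within 3 mismatches at most 1.56 RPM were found in a carrot library, under the 10 set for a carrot variant. A more distant form, a loss in the preparation specific to carrot and a low level in the plant stay open, and no biological explanation was tested.

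14 unlisted tags of 20 to 24 nt were at 50 or more RPM in cacao leaf, spinach leaf at 5 weeks and carrot leaf, AGTTACTAATTCATGATCTGGC first, with TCAAACGAGGAAAGGCTTACGGT 118-fold higher in carrot leaf than in root and ATGAACTAATTCAGACTGTG higher in root. Carry-over between these 3 libraries, which moves all tags of a library alike, is argued against. For each tag, the 200 most abundant other unlisted tags of the library of these 3 where it was highest were followed into the library of these 3 where it was lowest. At most 31.0% of them (upper limit 37.7) reached the same part of their level, under the 50% set. Carry-over from or into carrot root or spinach leaf at 3 weeks was not tested. Plastid RNA is a candidate source that stays open for the tags as a set. Of plastid 16S rRNA only the 5′ part was listed, and of the large plastid rRNA nothing, so other pieces of both would count as unlisted. Several tags are nested or end variants of each other and were counted separately, so a median can mix different sources. The tags' median carrot leaf to root ratio was 3.52 (quartiles 2.02 and 13.2), with single tags from 0.276 to 118. Listed plastid RNAs had a median of 21.6 and nuclear ones 0.977 with a maximum of 3.48. The bound first written, the lowest listed plastid RNA at 0.843, was met, but it lies below the nuclear median, so the label was changed from fits to cannot tell once the value was seen.

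Dicer-like enzymes leave duplexes with 2-nt 3′ overhangs, and complementary tag pairs were counted by overhang, with a hypothesis that such pairs outnumber each other overhang at least 2 to 1. They did not. A first count, with a window that favoured some overhangs, was replaced after it was seen by full complementarity over the overlap, and both counts missed that bound. For 21-nt tags the 2-nt 3′ overhang was the most frequent of 9 in every library, but its excess over the next was 1.15 times in cacao leaf at the least and 1.61 times in carrot root at the most. For 24-nt tags the ratio ran from 0.981 in cacao leaf to 1.37 in spinach leaf at 3 weeks. Longer overhangs need fewer matched bases, which favours them in this count. The 2-nt 5′ overhang needs as many as the 2-nt 3′ overhang, a comparison not set in advance. For 21-nt tags the 3′ against 5′ pairs were 282 against 89 in cacao leaf, 1339 against 503 and 275 against 56 in spinach leaf at 5 and 3 weeks, 10325 against 1767 in carrot leaf and 2943 against 551 in carrot root.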
